A study of Homo sapiens with 26 samples.

How the data were processed

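RNA was sequenced from 26 bulk libraries of 9 progenitor populations sorted from human cord blood, which the series describes as CD34-positive, with 3 libraries per population and 2 for MDP. Per the labels' protocols, low numbers of cells were sorted per population, RNA was bound to oligo(dT) beads and libraries were made with the SMARTer Ultra Low kit. Per the submitters' processing notes, reads were aligned with STAR to GRCh37, counted with featureCounts and normalized with DESeq2, with no versions stated. The deposited raw table holds counts per gene. The deposited normalized table holds a signal that equals each count divided by a DESeq2 size factor, checked by dividing the counts by size factors computed here. All tests started from the counts, and the normalized table was used for that check only.

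The table had 50400 gene rows. The 405 rows of sex-linked genes, with 0.237% of all counts, were removed after library sizes were summed. Libraries held 3651653 to 19687877 counts. Replicates differed by more than counting error, with a lowest chi-square per degree of freedom of 28.9 between 2 libraries of a population. The labels do not say whether replicates came from different donors or cultures, so p-values describe the spread between these samples. The protocol gives no molecular barcodes, so floors cover counting error only. A population with 0 counts in all its libraries was given a floor of 3 counts per library, and folds against it are printed as "at least".

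The fit of all libraries used edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr by population (minimum count 10, minimum total count 15), 1 coefficient per population and the quasi-likelihood F test. It tested 19364 genes with a common dispersion of 2.24, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The 11 comparisons were MPP against HSC, LMPP and CMP against MPP, GMDP against CMP and LMPP, MDP against GMDP, CDP against MDP, GMDP and BNK, MLP against LMPP, and BNK against MLP. An F test over all 9 populations, 16 tests of IRF8 and SPI1 against HSC, and a permutation F test of the log2 SPI1 to IRF8 ratio (1 CPM added, 100000 shuffles) were run beside them. Levels are mean CPM (counts scaled to equal library sizes by the TMM factors) with the SD over libraries.

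Before any count was seen, 18 gene lists were fixed: stem cell, erythroid and megakaryocytic, mast cell, eosinophil and basophil, granulocyte, monocyte, conventional dendritic cell, plasmacytoid dendritic cell, MHC class II, early lymphoid, B cell, NK, T and innate lymphoid cell, cell cycle, immediate early, red cell and platelet contamination, mature B and plasma cell, endothelial and stromal cell, surface receptors used to sort progenitors, and transcription factors of blood lineages. Of their 418 genes, 415 matched a row. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with the correlation estimated, with adjustment over all 198 tests. Named genes followed a rule fixed before the data: IRF8 and SPI1 in every comparison, the 8 called genes with the largest log2 fold change each way among those at 10 CPM or more with a log2 change of at least 1 and no overlap between groups, and up to 4 called or 2 uncalled members of each list. The text prints part of them.

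Alternatives were RLE factors, no filter, DESeq2 1.42.0, limma-voom with quality weights, a fit of only the 2 populations compared, each library left out in turn, and pseudocounts of 0.5 and 5 CPM. Added after the data were seen were fits without the 4 libraries under 6000 genes detected, without the 10 under 12000, with the log2 number of genes detected as a covariate, and with the MIR4485 row out of the library sizes. In the fit without the 10 libraries, MPP and MDP had 1 library each, which was assumed to vary like the other groups. Splits of the same libraries into other groups and shuffled population labels gave chance counts.

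The tests were tested on simulated data in which every population was given the mean of each gene over all libraries, with the fitted dispersions and library sizes, and 200 genes at 10 CPM or more were changed in 1 population. For CDP against GMDP, edgeR recovered 1 of 67 genes changed 4-fold, 11 of 67 changed 16-fold and 29 of 66 changed 64-fold among 17859 genes, with 0 unchanged genes called. DESeq2 called 132 unchanged genes and limma-voom 23. Counts were drawn for each gene and library on their own, so no simulated library misses many genes together. The 0 false calls therefore do not cover libraries with few genes detected, as in CDP. For GMDP against CMP the numbers for edgeR were 1, 8 and 30 among 17943 genes, with 0 unchanged genes called, and DESeq2 called 186 unchanged genes and limma-voom 20. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.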

Results

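Gene expression was measured by RNA sequencing in 9 blood progenitor populations sorted from human cord blood. The populations were haematopoietic stem cells (HSC), multipotent progenitors (MPP), lymphoid-primed multipotent progenitors (LMPP), common myeloid progenitors (CMP), GMDP, monocyte and dendritic cell progenitors (MDP), common dendritic cell progenitors (CDP), multilymphoid progenitors (MLP) and B and natural killer cell progenitors (BNK). The labels describe GMDP only as a monocyte and dendritic cell progenitor with a leading G. Each population had 3 libraries except MDP, which had 2, giving 26 libraries. The labels do not state whether replicates came from different donors, so every p-value measures the spread between these samples.

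Libraries held 3651653 to 19687877 counted reads. The number of genes with a read ranged from 3775 to 21636, and it differed between replicates of the same population. HSC replicate 1 detected 3981 genes, while HSC replicates 2 and 3 detected 19810 and 20722. The CDP libraries detected 5677, 5784 and 3775 genes, and the BNK libraries detected 20508, 21636 and 17903. In all, 10 libraries had fewer than 12000 genes with a read. These were HSC 1, MPP 2 and 3, LMPP 2, CMP 3, MDP 2, CDP 1, 2 and 3, and MLP 1. A single row, MIR4485, took 2.72% to 58.8% of the counts of a library. This annotated microRNA transcript of 57 bases matched the transcript of MTRNR2L8, a nuclear copy of the mitochondrial ribosomal RNA, with 0 mismatches and the mitochondrial ribosomal RNA MT-RNR2 with 4. Reads in that row can come from any of these sources, so its level is not read as microRNA expression.

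**Figure D1:**
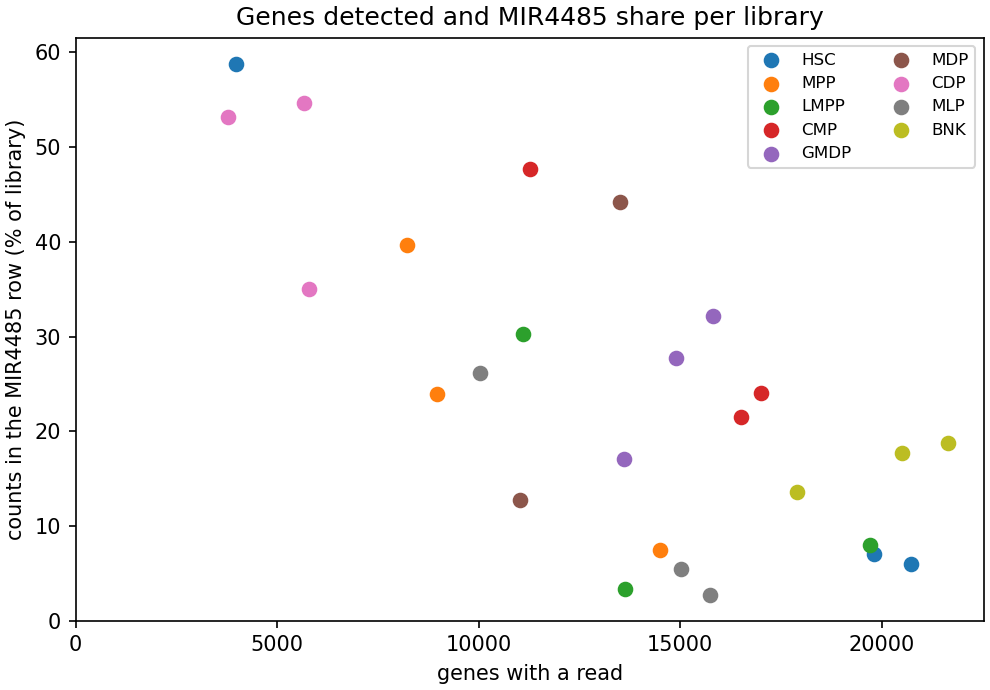
Genes with a read (x axis) against the percentage of the counts of each library in the MIR4485 row (y axis), 1 point per library, coloured by population. The CDP libraries and HSC replicate 1 lie at the left, with 3775 to 5784 genes.

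IRF8 and SPI1 came first because the title of the series names the dosage of PU.1, the protein of SPI1, and of IRF8 in HSC. Both encode transcription factors of myeloid, dendritic and B cells. IRF8 was low in HSC at 7.86 ± 6.82 CPM (SD, n = 3), in MPP at 3.42 ± 5.75 (n = 3) and in CMP at 1.93 ± 1.70 (n = 3). HSC replicate 1, with 3981 genes, had 0 reads of IRF8, and HSC replicates 2 and 3 were at 12.03 and 11.56 CPM. That library pulls down the HSC mean, the reference of the folds against HSC. MPP replicates 2 and 3 had 1 read of IRF8 each, and MPP replicate 1 was at 10.07 CPM. IRF8 stood at 39.9 ± 16.6 CPM in GMDP (n = 3), 94.4 ± 75.7 in LMPP (n = 3) and 129 ± 1.38 in MDP (n = 2). LMPP replicate 2 was at 7.81 CPM, under HSC replicates 2 and 3, while LMPP replicates 1 and 3 were at 127 and 148. The highest means were 202 ± 80.6 CPM in MLP, 219 ± 89.0 in BNK and 411 ± 260.1 in CDP (n = 3 each). Against HSC, edgeR's quasi-likelihood test with adjustment over the 16 tests of both genes called IRF8 higher in LMPP (adjusted p = 0.0448), MDP (0.0379), MLP (0.0150), BNK (0.0150) and CDP (0.0107). The log2 fold changes were 3.58 in LMPP, 4.03 in MDP, 4.68 in MLP, 4.79 in BNK and 5.70 in CDP, with standard errors of 1.39, 1.47, 1.46, 1.47 and 1.53. Each of the 5 calls was lost without HSC replicate 2 (adjusted p = 0.0503 to 0.0900) or 3 (0.0563 to 0.0993) and with only the 2 populations compared in the fit (0.0581 to 0.154), and those in LMPP and MDP also without HSC replicate 1 (0.0912 and 0.0723). The call in LMPP was also lost without LMPP replicate 1 (0.0990) or 3 (0.125). Adjusted over all genes tested, IRF8 passed the threshold only in CDP (adjusted p = 0.0144).

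SPI1 spread over a narrower range of means, from 26.02 ± 23.9 CPM in HSC (n = 3) to 114 ± 28.2 in MDP (n = 2). HSC replicate 1, with 3981 genes, had 1 read of SPI1 and pulls the HSC mean down, HSC replicates 2 and 3 being at 47.1 and 30.8 CPM. It was 50.7 ± 5.64 CPM in MPP, 72.4 ± 26.4 in LMPP, 72.7 ± 26.6 in CMP, 81.2 ± 13.7 in GMDP, 57.5 ± 80.9 in CDP, 34.8 ± 7.75 in MLP and 62.2 ± 17.01 in BNK (n = 3 each). None of the 8 contrasts of SPI1 against HSC passed the threshold over the 16 tests in edgeR, the smallest adjusted p being 0.268. A fit chosen after the data were seen kept the 16 libraries with at least 12000 genes detected. In it SPI1 was above HSC at log2 fold changes of 1.77 in MDP and 1.06 in GMDP. MDP had 1 library there, so only its fold is given, which does not mean that it failed the test. The fold in GMDP passed with adjustment over the IRF8 and SPI1 tests of that fit, but not over all genes tested. The log2 ratio of SPI1 to IRF8, with 1 CPM added to each, averaged 4.84 ± 1.61 in CMP and 4.44 ± 1.86 in MPP. It was 1.14 ± 0.87 in HSC, 1.08 ± 0.86 in GMDP, 0.33 ± 2.55 in LMPP, -0.20 ± 0.37 in MDP, -1.74 ± 0.77 in BNK, -2.45 ± 0.85 in MLP and -4.57 ± 4.35 in CDP. IRF8 had 0 or 1 read in HSC replicate 1, MPP replicates 2 and 3 and CMP replicate 3. SPI1 had 0 or 1 read in HSC replicate 1 and CDP replicate 1. The ratio in these libraries depends on the 1 CPM added. The ratio differed across the 9 populations in a one-sided permutation test of the F ratio over 100000 shuffles of the labels (F = 6.93, p = 4e-05). Pairs of populations with 3 libraries each cannot reach p under 0.05 in such a test and were not tested.

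**Figure D2:**
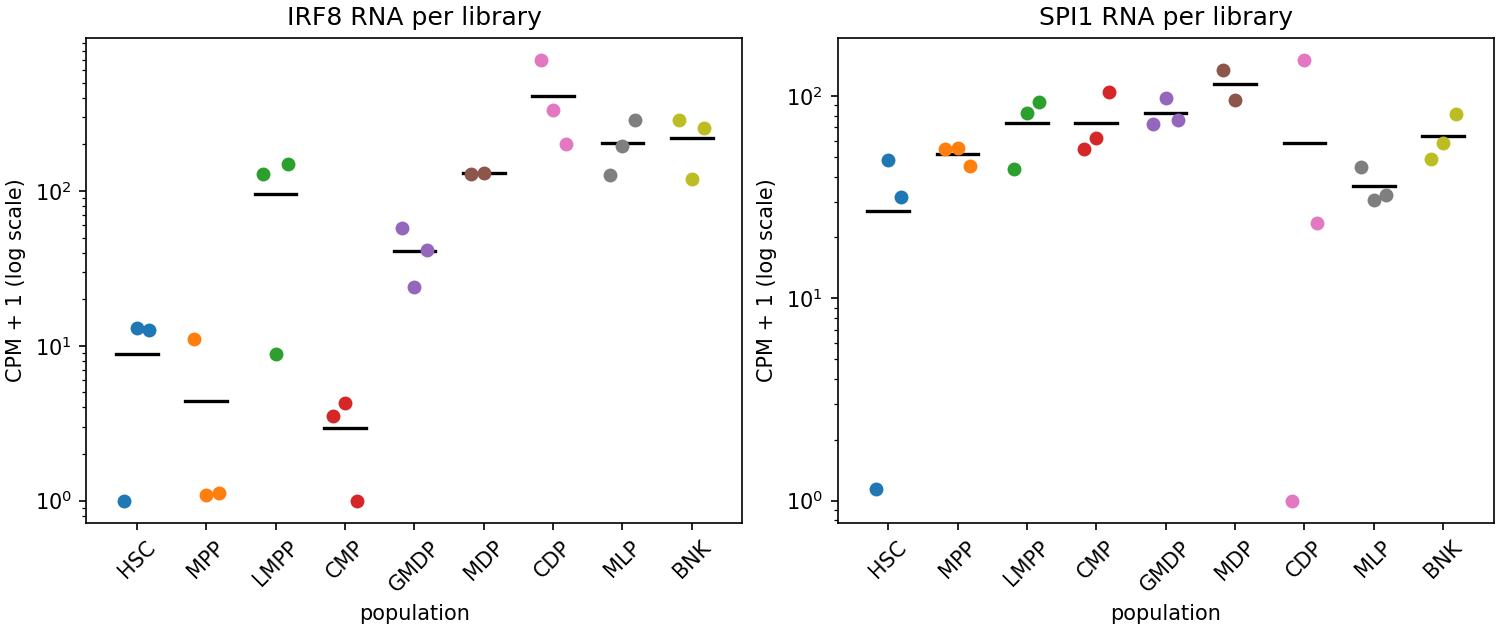
IRF8 (left) and SPI1 (right) RNA in CPM plus 1 on a log scale, 1 point per library and a black line at the mean of each population. IRF8 means ran from 1.93 CPM in CMP to 411 in CDP, and SPI1 means from 26.02 in HSC to 114 in MDP.

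Across all 9 populations, edgeR called 485 of the 19364 genes tested as varying, and 4319 had an unadjusted p under 0.05. Sets of shuffled population labels each called genes too, from 90 to 512, so part of the 485 can be false calls. The mean level was highest in CDP for 134 of the 485, in HSC for 89, in MPP for 58, in MLP for 52, in CMP for 45, in BNK for 43, in MDP for 31, in GMDP for 27 and in LMPP for 6. The 10 genes with the largest F were looked up after their values were seen. CD34, the surface marker of blood progenitors, was at 307 ± 107 CPM in GMDP, 253 ± 62.3 in HSC and 0 in all 3 CDP libraries (F = 13.2, adjusted p = 3.97e-08). NPR3, a natriuretic peptide receptor, was at 340.1 ± 173 CPM in HSC and 0.0910 ± 0.158 in CDP. IL7R, the interleukin 7 receptor, was at 219.6 ± 138 CPM in BNK and 15.1 ± 7.45 in MLP, and EBF1, a B cell transcription factor, at 161 ± 97.1 in BNK and 27.3 ± 4.53 in MLP. SLC2A5, a fructose transporter, was at 300.5 ± 158 CPM in MLP. NCOA7, a nuclear receptor coactivator, was at 552 ± 208 CPM in MLP and 0.109 ± 0.0979 in CDP, and CCND2, a cell cycle cyclin, at 448 ± 9.97 in CMP and 0.172 ± 0.192 in CDP. PTGDS, a prostaglandin synthase, PLXNA4, a semaphorin receptor, and TGFBI, an extracellular matrix protein, had their highest means in CDP at 73.7 ± 109, 154 ± 267 and 94.2 ± 141 CPM. Most of that came from CDP replicate 1, with 199, 463 and 256 CPM, and PLXNA4 had 0 counts in CDP replicates 2 and 3. Leaving out CDP replicate 3 left 292 varying genes and leaving out MPP replicate 3 left 320, whereas leaving out MDP replicate 1 gave 1552 and MDP replicate 2 gave 1233.

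The lists of marker genes, 18 in all, were fixed before the data were examined. In the same F test, shuffled labels called 4 to 23 list genes, against 50 with the real labels. In the stem cell list, 9 of 28 genes varied across populations and 13 varied adjusted over the list alone, with NPR3, MECOM, HLF and NRIP1 at the largest F. In the granulocyte list, PRTN3, ELANE, MPO and RNASE2 led 5 of 16 genes, with 14 adjusted over the list alone. IL7R, IGJ (an older symbol of JCHAIN), RAG2 and MME led 8 of 23 early lymphoid genes (10 adjusted over the list alone), and EBF1, AKAP12, BLNK and POU2AF1 led 5 of 23 B cell genes (13 adjusted over the list alone). TRIB2, CYTL1, KLF1 and SLC40A1 were the 4 of 28 erythroid and megakaryocytic genes called (8 adjusted over the list alone), and CPA3 and IL1RL1 the 2 of 14 mast cell, eosinophil and basophil genes (12 adjusted over the list alone). CYBB, VCAN and LYZ were the 3 of 23 monocyte genes (8 adjusted over the list alone), CLEC10A, ID2 and IRF4 the 3 of 19 conventional dendritic cell genes (9 adjusted over the list alone), and BLNK, SPIB and PACSIN1 the 3 of 20 plasmacytoid dendritic cell genes (7 adjusted over the list alone). EBF1, MECOM, HLF and IRF8 led 11 of 57 transcription factors of blood lineages (13 adjusted over the list alone), and CD34, IL7R, MME and CSF3R were the 4 of 14 surface receptors used in sorting (8 adjusted over the list alone). EGR3 and EGR2 were the 2 of 19 immediate early genes (3 adjusted over the list alone), ID2 the 1 of 21 NK, T and innate lymphoid genes (3 adjusted over the list alone), and TNFRSF13B and IRF4 the 2 of 8 mature B and plasma cell genes (2 adjusted over the list alone). HBG2 was the 1 of 12 red cell and platelet genes and PDGFRB the 1 of 9 endothelial and stromal genes, each also 1 adjusted over the list alone. None of the 13 MHC class II genes or the 30 cell cycle genes was called by edgeR in this F test by either adjustment, with 1 and 8 at an unadjusted p under 0.05. This lack of calls does not show equal levels. The fit of 16 libraries given below called 7 of 30 cell cycle genes lower in MLP than in LMPP and 6 of 30 higher in BNK than in MLP.

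**Figure D3:**
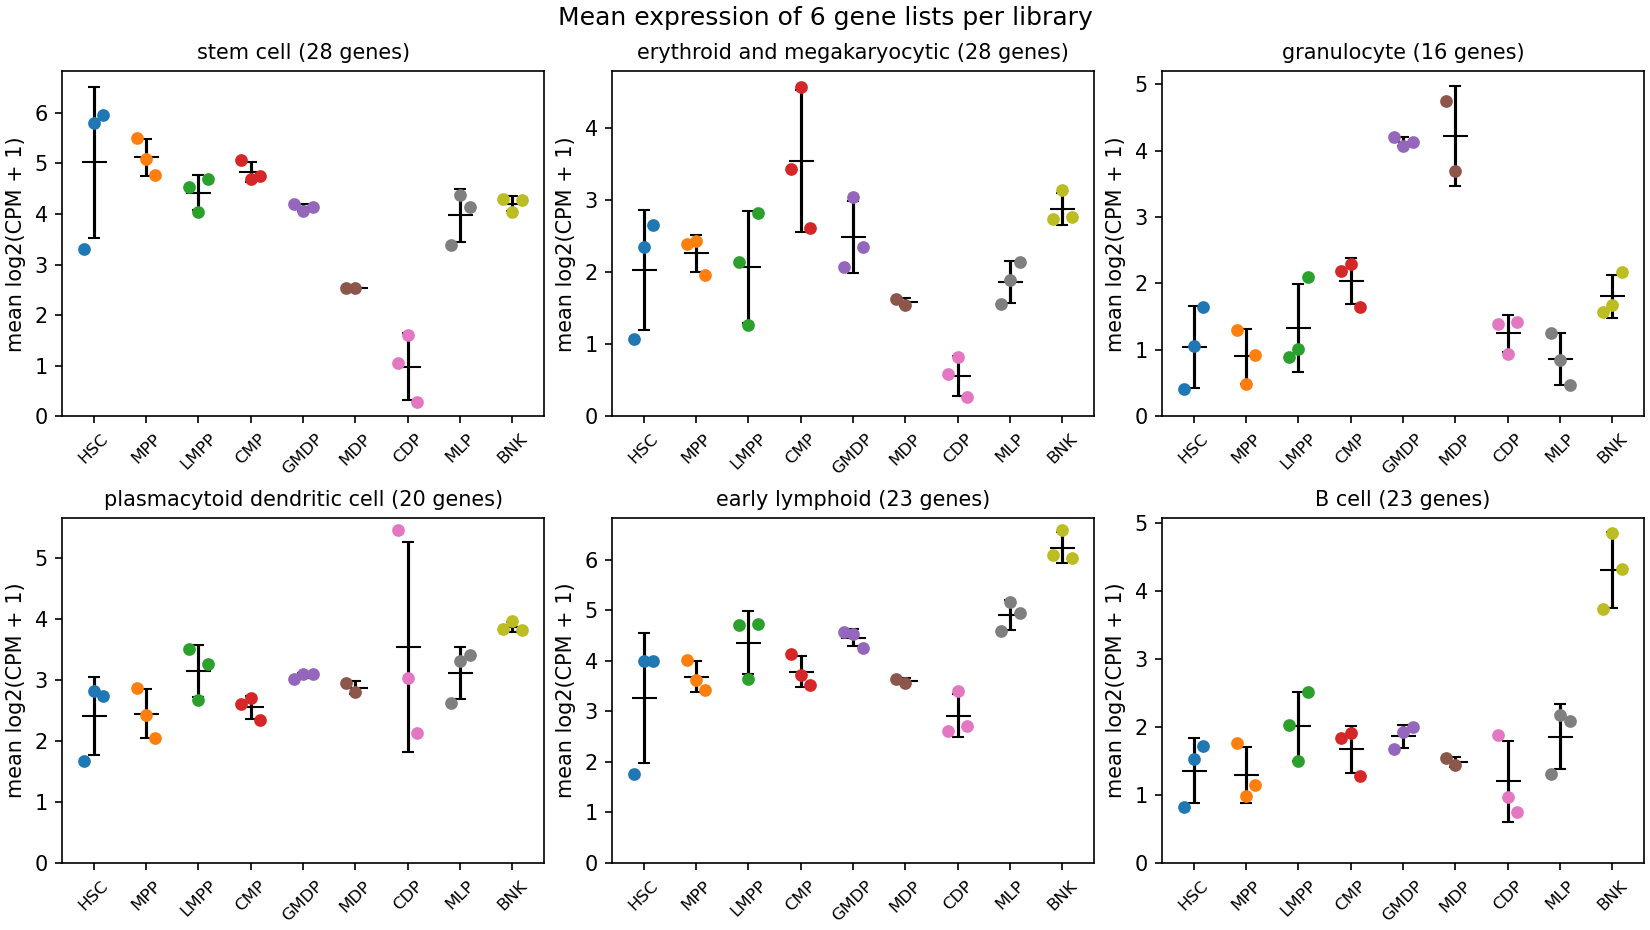
Mean log2(CPM + 1) of the genes of 6 lists in each library (points), with the mean and SD of each population (black). Granulocyte genes were highest in GMDP and MDP, B cell and early lymphoid genes in BNK, and stem cell genes lowest in CDP.

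Pairwise comparisons followed the usual order of the populations. The same edgeR fit of all 26 libraries called 0 genes in the 8 comparisons that leave out CDP, although 758 to 1590 genes had an unadjusted p under 0.05 in each. On simulated counts for GMDP against CMP, the edgeR test recovered 1 of 67 genes changed 4-fold, 8 of 67 changed 16-fold and 30 of 66 changed 64-fold, with 0 unchanged genes called. That simulation did not model libraries that miss many genes together. On the real counts, edgeR called 919 genes in another split of the MPP and HSC libraries. A second fit kept the 16 libraries with at least 12000 genes detected. It was chosen after the data were seen, named its genes by the same rule, and had an estimated common dispersion of 0.887 against 2.24 with all libraries. It holds no CDP library and only 1 MPP and 1 MDP library, each assumed to vary like the other groups. The simulation and the splits into other groups were not run on this second fit, so its share of false calls is not known. The preset correlation of camera called 67 of 198 tests of a list in a comparison, 34 higher and 33 lower, of which 3 were past the threshold with a correlation estimated from the data.

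**Figure D4:**
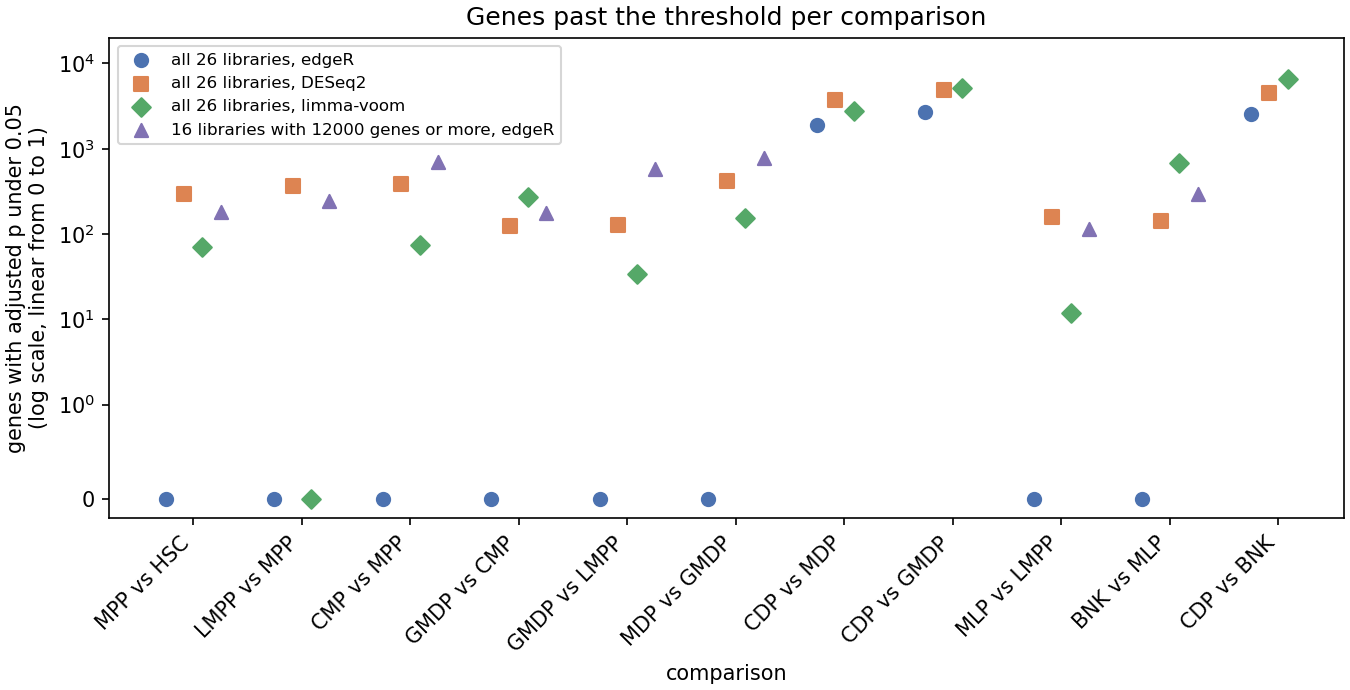
Genes with an adjusted p under 0.05 per comparison (y axis, log scale with a linear part from 0 to 1) by edgeR, DESeq2 and limma-voom on all 26 libraries and by edgeR on the 16 libraries with at least 12000 genes. The edgeR fit of all libraries called 0 genes outside the CDP comparisons, and the 16 libraries gave 115 to 777.

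MPP and HSC were compared for the first step away from stem cells. NRIP1 and MEIS1, genes of the stem cell programme, were abundant in both, at 2057 ± 587 CPM in MPP and 1523 ± 391 in HSC for NRIP1 and 358 ± 31.1 and 426 ± 328 for MEIS1 (n = 3 each). LYZ, the lysozyme of monocytes and granulocytes, was at 197 ± 214 CPM in MPP and 8.79 ± 11.1 in HSC, and CTSS, a cathepsin of antigen-presenting cells, at 107 ± 79.5 and 24.2 ± 21.7. IRF8 and SPI1 had adjusted p of 1 and 1. With edgeR, 0 genes passed and 1290 had an unadjusted p under 0.05. DESeq2 called 19 higher and 272 lower, and limma-voom 0 and 71. The monocyte list was called higher by camera (median log2 fold change 3.67, or 3.02 with undetected genes at their bound, adjusted p = 3.27e-06), with adjusted p = 0.369 with an estimated correlation. Its genes were highest in MPP replicates 2 and 3, and in the 16 libraries, with the lone MPP replicate 1, its adjusted p was 0.961. The red cell and platelet list was also called higher (10 of 12 genes, median 2.70, adjusted p = 0.0237; 0.609 with an estimated correlation), and in the 16 libraries its median turned to -2.36 (adjusted p = 0.553). The 16 libraries gave 53 genes higher and 129 lower.

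LMPP against MPP addressed lymphoid priming. IRF8 was at 153 ± 17.3 CPM in the 2 LMPP libraries kept in the fit of 16 and 11.1 in the lone MPP library (log2 fold change 3.78 ± 0.55 SE, adjusted p = 1.94e-08). In the fit of all libraries it was at 94.4 ± 75.7 and 3.42 ± 5.75 CPM and did not pass (adjusted p = 0.606). LMPP replicate 2 was at 7.81 CPM there and is not among the 16 libraries. EBF1 was at 23.2 ± 9.02 CPM in LMPP and 0 in MPP, at least 76.3-fold higher against a floor of 3 counts, and IGJ, which joins antibody chains, was at 13.5 ± 6.09 and 0, at least 44.4-fold higher. CD44, an adhesion receptor, rose from 176 to 539 ± 34.8 CPM, while MECOM, a stem cell transcription factor, fell from 138 to 16.2 ± 3.32, NR4A1, an immediate early gene, from 217 to 46.9 ± 29.6 and the MHC class II gene HLA-DRB5 from 159.5 to 21.9 ± 9.94. SPI1 did not differ by that test (adjusted p = 0.971). These 16 libraries gave 161 genes higher and 83 lower, and in them camera called the red cell and platelet list higher (median 4.48, adjusted p = 0.00194; 0.399 with an estimated correlation). With all libraries, MPP replicates 2 and 3 included, that list had the opposite sign (median -0.99, 10 of 12 genes lower, adjusted p = 0.674). On all libraries edgeR called 0 genes with 1590 at an unadjusted p under 0.05, DESeq2 327 higher and 36 lower, and limma-voom 0. The stem cell list was lower by camera (median -1.01, adjusted p = 8.87e-06), with adjusted p = 0.369 with an estimated correlation. The immediate early list, whose genes also respond to handling, was lower in 17 of 19 genes (median -1.75, adjusted p = 4.88e-10) and the monocyte list in 22 of 23 (-2.68, 4.7e-09), with adjusted p = 0.127 and 0.266 with an estimated correlation. Without MPP replicates 2 and 3, in the 16 libraries, these lists had adjusted p of 0.0779 and 0.855.

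CMP against MPP addressed the myeloid branch. In the 16 libraries, CPA3 and HDC, a protease and a histidine decarboxylase of mast cells, rose from 0.809 to 61.5 ± 26.7 and from 16.1 to 145 ± 2.28 CPM (2 CMP libraries against the lone MPP library). TOP2A, a topoisomerase of dividing cells, rose from 6.88 to 54.0 ± 9.02. HLA-DQB1 fell from 389 to 42.5 ± 36.2, HLA-DRB5 from 159.5 to 18.1 ± 2.34 and FLT3, a growth factor receptor of early progenitors, from 156 to 49.0 ± 1.07. IRF8 was at 11.1 CPM in that MPP library and 3.18 ± 0.571 in CMP (log2 fold change -1.79, adjusted p = 0.00771). The call rests on MPP replicate 1, since MPP replicates 2 and 3 had 1 read of IRF8 each. Over all libraries the log2 fold change of IRF8 turned to 4.15 without MPP replicate 1 (adjusted p = 0.214) and to 1.81 with limma-voom (0.790). SPI1 did not pass in the 16 libraries (59.3 and 63.2 ± 6.18 CPM, adjusted p = 1). The fit of 16 gave 335 genes higher and 363 lower. On all libraries edgeR called 0 genes with 1522 at an unadjusted p under 0.05, DESeq2 322 higher and 61 lower, and limma-voom 70 and 4. The lists of cell cycle genes (median 2.57, adjusted p = 1.37e-06) and mast cell genes (2.74, 4.64e-06) were higher and MHC class II lower (-0.75, 5.15e-05) by camera. The monocyte list (-1.59, 1.14e-04) and the immediate early list (-0.46, 5.68e-04) were lower as well. With an estimated correlation none of these 5 lists passed, and in the 16 libraries, without MPP replicates 2 and 3, the monocyte and immediate early lists had adjusted p of 0.281 and 0.961.

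GMDP against CMP compared populations that both have myeloid output. In the 16 libraries (3 GMDP, 2 CMP), MPO, the myeloperoxidase of neutrophil granules, rose from 91.8 ± 4.84 to 2079 ± 456 CPM (adjusted p = 7.73e-26). The granule proteases PRTN3, ELANE and AZU1 rose from 4.203 ± 3.09 to 114 ± 51.1, from 1.67 ± 0.883 to 54.5 ± 8.26 and from 1.94 ± 0.0169 to 34.7 ± 18.3 CPM. IRF8 rose from 3.18 ± 0.571 to 44.2 ± 18.2 (log2 fold change 3.78 ± 0.41 SE, adjusted p = 1.67e-16), LYZ from 21.7 ± 3.13 to 99.1 ± 24.8, IL7R from 0.121 ± 0.170 to 7.27 ± 1.83 and FLT3 from 49.0 ± 1.07 to 122 ± 27.1. HDC fell from 145 ± 2.28 to 1.67 ± 2.03 CPM and GATA2, a transcription factor of the erythroid and mast cell branches, from 403 ± 173 to 96.1 ± 40.8. CNRIP1, KLF1 and IL1RL1, markers of the erythroid, megakaryocytic and mast cell branches, were at 0 in all 3 GMDP libraries and at least 157-fold, 64.7-fold and 61.7-fold lower. The stem cell gene HLF fell from 51.4 ± 28.5 to 12.2 ± 4.09 CPM. SPI1 did not pass (adjusted p = 0.855).

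That fit called 77 genes higher and 97 lower in GMDP, against 0 on all libraries, where edgeR gave 758 at an unadjusted p under 0.05, DESeq2 49 higher and 74 lower and limma-voom 55 and 216. On simulated counts for this comparison DESeq2 called 186 unchanged genes and limma-voom 20, so their counts can hold false calls. On all libraries camera called the granulocyte list higher (median 3.69, or 1.84 with undetected genes at their bound, adjusted p = 8.72e-13), also with an estimated correlation (adjusted p = 0.0380). In the 16 libraries camera called that list higher at the preset correlation but not with an estimated one (adjusted p = 0.0781). The mast cell list (-1.39, 5.97e-08) and the erythroid and megakaryocytic list (-1.77, or -1.44 at the bound, 1.31e-06) were lower, with adjusted p = 0.0704 and 0.369 with an estimated correlation. Of the 14 mast cell list genes 2 were higher, among them CPA3 (57.6 ± 48.3 CPM in GMDP and 43.1 ± 27.9 in CMP, log2 fold change 0.42, adjusted p = 1).

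GMDP against LMPP set the myeloid against the lymphoid-primed population. In the 16 libraries (3 GMDP, 2 LMPP), PRTN3 rose from 0.785 ± 1.11 to 114 ± 51.1 CPM and MPO from 102 ± 114 to 2079 ± 456, with ELANE, AZU1 and RNASE2, an eosinophil and neutrophil ribonuclease, at log2 fold changes of 5.11, 4.50 and 4.86. LYZ rose from 8.03 ± 11.2 to 99.1 ± 24.8 CPM and MKI67, a marker of dividing cells, from 85.8 ± 47.6 to 313 ± 68.2. The lymphoid genes MME, CD22 and EBF1 fell from 40.4 ± 38.3 to 6.46 ± 2.27, from 45.4 ± 27.2 to 6.35 ± 2.32 and from 23.2 ± 9.02 to 2.55 ± 2.23 CPM, and the stem cell genes HLF and MEIS1 from 73.8 ± 3.85 to 12.2 ± 4.09 and from 235 ± 17.5 to 81.0 ± 43.5. LMPP replicate 2, not among the 16 libraries, had IRF8 at 7.81 CPM in the fit of all libraries. In the 16 libraries IRF8 fell from 153 ± 17.3 to 44.2 ± 18.2 CPM (log2 fold change -1.79 ± 0.33 SE, adjusted p = 1.8e-05) and SPI1 did not pass (adjusted p = 0.868). That fit gave 169 genes higher and 416 lower. On all libraries edgeR called 0 with 957 at an unadjusted p under 0.05, DESeq2 22 higher and 106 lower, and limma-voom 10 and 24. There camera called the granulocyte list higher (median 4.85, or 4.28 at the bound, adjusted p = 4.4e-21), also with an estimated correlation (adjusted p = 0.00961). It called the cell cycle list higher too (1.39, 3.11e-07), but not with an estimated correlation. In the 16 libraries camera called the granulocyte list higher at the preset correlation but not with an estimated one (adjusted p = 0.0781).

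MDP against GMDP addressed the step toward monocytes and dendritic cells. Between the lone MDP library and 3 GMDP libraries of the fit of 16, LYZ was at 564 and 99.1 ± 24.8 CPM, AZU1 at 210.3 and 34.7 ± 18.3, CLEC12A, a myeloid lectin, at 161 and 24.5 ± 10.2 and IRF8 at 141 and 44.2 ± 18.2, all called higher. CD34 fell from 343 ± 124 to 59.2 CPM and GATA2 from 96.1 ± 40.8 to 14.0. MYH10, a non-muscle myosin, MMRN1, a megakaryocyte and stem cell protein, and HLF were at 0 in that MDP library, at least 50.7-fold, 34.7-fold and 15.2-fold lower. SPI1 did not pass (adjusted p = 0.565). LYZ differed between the 2 MDP libraries, at 263 ± 355 CPM in the fit of all libraries, and its log2 fold change went from 1.56 to -2.81 without MDP replicate 1, the library kept in the fit of 16. That fit gave 216 genes higher and 561 lower. On all libraries edgeR called 0, with 920 at an unadjusted p under 0.05 and MYH10 at the smallest adjusted p (0.0827). Without MDP replicate 1 it called 8 higher and 15 lower, and without MDP replicate 2 it called 19 higher and 0 lower. DESeq2 gave 34 higher and 383 lower and limma-voom 41 and 113. The stem cell list was lower by camera (median -1.80, adjusted p = 4.84e-07; 0 of 28 genes past the threshold and 4 adjusted over the list alone), with adjusted p = 0.200 with an estimated correlation. The red cell and platelet list was lower too (10 of 12 genes, median -2.85, or -2.49 at the bound, adjusted p = 0.0237; 0.609 with an estimated correlation). The granulocyte list did not fall with them: 11 of its 16 genes were higher in MDP and 5 lower (median 0.22, camera adjusted p = 0.338). The median over all genes was -0.02, and -0.12 with RLE factors.

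CDP was compared with GMDP, MDP and BNK in the fit of all libraries, in which every CDP library had few genes detected. Against GMDP, CD34 was lower in CDP, from 307 ± 107 CPM to 0 counts in all 3 libraries (at least 387-fold, adjusted p = 6.38e-11). HSC replicate 1, with as few genes, had 1317 counts of CD34. The series describes its cells as CD34-positive, and the labels give no gate for CDP. Angiopoietin gene ANGPT1 (129.7 ± 7.75 CPM in GMDP), the transcription factor LMO2 (84.5 ± 15.2), the mast cell enzyme HPGDS (65.3 ± 23.0), the stem cell genes FGD5 (31.6 ± 9.20) and HOXA5 (27.9 ± 17.1), the erythroid factor NFE2 (38.0 ± 14.8), the granule protease PRTN3 (102 ± 45.7), and CEBPB (25.97 ± 5.79) and ID2 (17.8 ± 3.67), transcription factors of monocytes and of dendritic cells, were also at 0 in all CDP libraries. So were the housekeeping genes RPS13 (156 ± 55.3 CPM in GMDP), of the ribosome, and COX6C (133 ± 48.7), of the respiratory chain. With such genes at 0, loss of transcripts stays possible. Folds of "at least" in CDP therefore bound the counts and not the change in the cells. KIT, a growth factor receptor, fell from 116 ± 32.9 to 9.07 ± 15.5 CPM and CD44 from 508 ± 169 to 83.0 ± 21.0. KIT lost its call without CDP replicate 1 (adjusted p = 0.0549) or 3 (0.0529).

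Genes called higher in CDP than in GMDP were few. TCF4, a transcription factor of plasmacytoid dendritic cells, was at 839.9 ± 541 CPM in CDP and 217 ± 26.7 in GMDP (log2 fold change 1.95 ± 0.62 SE, adjusted p = 0.0265). SOX4, a transcription factor of progenitors, was at 1808 ± 892 and 458 ± 71.7, HLA-DMB, which loads peptides onto MHC class II, at 348 ± 261 and 34.3 ± 16.7, and CYTH4, EZR and RAB11FIP1, of membrane traffic and the cell cortex, at 322 ± 121 and 44.4 ± 18.6, 865 ± 390.2 and 237 ± 126, and 508 ± 145 and 42.6 ± 14.7. MYBPC2, a myosin-binding protein, was at 52.9 ± 19.3 and 0, at least 214-fold higher. Without CDP replicate 1 the adjusted p was 0.140 for TCF4, 0.0671 for SOX4, 0.0699 for HLA-DMB, 0.0925 for EZR and 0.0883 for RAB11FIP1, and each of these except SOX4, and CYTH4, also lost its call without at least 1 GMDP library. IRF8 did not pass (log2 fold change 3.37, adjusted p = 0.0903), nor did SPI1 (-0.50, 0.947). In all, edgeR called 87 genes higher and 2617 lower, and 2084 of the lower genes were at 0 in all 3 CDP libraries. Leaving out CDP replicate 3 gave 31 higher and 1763 lower, GMDP replicate 1 10 and 2010, and GMDP replicate 2 10 and 1995. With the number of genes detected as a covariate, chosen after the data were seen, 241 were higher and 383 lower. TCF4, CD34, ANGPT1, RPS13, COX6C, LMO2, FGD5 and HOXA5 kept their calls there, the other 13 named genes lost theirs (adjusted p = 0.0810 to 0.577), and IRF8 passed (log2 fold change 10.04, adjusted p = 1.43e-04). Outside CDP only HSC replicate 1 had under 6000 genes, so this fit cannot separate the number of genes from CDP. Its fold of IRF8 lies far above the ratio of the mean levels, 411 CPM in CDP and 39.9 in GMDP. The stem cell list had 13 of 28 genes lower (18 adjusted over the list alone) and a median log2 fold change of -5.29, or -2.94 with undetected genes at their bound. Camera called it lower (adjusted p = 4.76e-05) and the plasmacytoid dendritic cell list higher (median 1.54, 9.07e-04), both without passing with an estimated correlation. The plasmacytoid list was high in CDP replicate 1 only, with a mean log2(CPM + 1) of 5.46, 3.03 and 2.13 in CDP replicates 1, 2 and 3 and 3.02 to 3.09 in GMDP. The median over all genes was -1.88, and -1.72 with RLE factors.

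Against MDP, SOX4 was at 1808 ± 892 CPM in CDP and 315.5 ± 162 in MDP (n = 2) and AMICA1, a junction adhesion molecule, at 77.8 ± 34.6 and 4.05 ± 5.72, both called higher. CYBB, of the phagocyte oxidase, was at 90.2 ± 67.4 and 0, SERPINF1, a secreted serpin, at 61.7 ± 34.9 and 0, and PACSIN1, a plasmacytoid dendritic cell gene, at 56.7 ± 98.3 and 0, at least 164-fold, 113-fold and 103-fold higher. All PACSIN1 counts in CDP came from CDP replicate 1. CD34 was at least 46.2-fold lower from 36.7 ± 24.3 CPM, PRTN3 at least 145-fold from 115 ± 104, ELANE at least 96.1-fold from 76.3 ± 79.0, LMO2 at least 94.8-fold from 75.2 ± 33.6, the splicing helicase DHX15 at least 131-fold from 104 ± 40.4 and the histone mRNA binding protein SLBP at least 129-fold from 102 ± 80.3. CSF3R, the receptor of granulocyte colony-stimulating factor, fell from 792 ± 88.2 to 124 ± 21.7 CPM and KIT from 128 ± 19.99 to 9.07 ± 15.5. SOX4, AMICA1 and CSF3R lost their calls without MDP replicate 2 (adjusted p = 0.124, 0.264 and 0.09996), ELANE without MDP replicate 1 (0.0577), KIT without CDP replicate 1 (0.0664) or 3 (0.0615), and CYBB, SERPINF1 and PACSIN1 without either MDP library. CYBB also lost its call without CDP replicate 1 (0.0535) or 2 (0.0719), and SERPINF1 without CDP replicate 2 (0.0639). IRF8 (1.67, adjusted p = 0.615) and SPI1 (-0.99, 0.896) did not pass. In all, 17 genes were higher and 1889 lower, of which 1511 were at 0 in all CDP libraries. Without MDP replicate 1 the numbers were 28 and 1296, and with the covariate 163 and 386. The covariate ended the calls of SOX4, AMICA1, PRTN3, ELANE, CSF3R and KIT (adjusted p = 0.0750 to 0.569), while IRF8 passed with it (7.02, 0.00809). Here too the covariate cannot be separated from CDP. The granulocyte list was lower by camera (median -6.16, or -3.32 at the bound, adjusted p = 1.62e-04; 3 of 16 genes and 8 adjusted over the list alone), with adjusted p = 0.369 with an estimated correlation. Camera called the plasmacytoid dendritic cell list (median 1.34, adjusted p = 1.53e-04) and the MHC class II list (1.58, 0.00184) higher. With an estimated correlation their adjusted p was 0.369 and 0.463. The plasmacytoid list was highest in CDP replicate 1, as given above. The median over all genes was -0.44, and -0.09 with RLE factors, so changes under this shift have no direction of their own.

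Against BNK, the lymphoid genes DNTT, the terminal transferase, IL7R, EBF1, PAX5, a B cell factor, and LTB, lymphotoxin beta, were at 0 in all CDP libraries. They stood at 238 ± 186, 219.6 ± 138, 161 ± 97.1, 36.0 ± 23.4 and 70.3 ± 12.04 CPM in BNK (n = 3), at least 300.1-fold, 277-fold, 202-fold, 45.3-fold and 88.5-fold lower. CD34, SLC2A5 and LMO2 were at least 243-fold, 173-fold and 66.1-fold lower. The dendritic cell and antigen presentation genes TCF4 (839.9 ± 541 in CDP, 447 ± 42.05 in BNK) and CD74 (1736 ± 1070.3 and 1531 ± 244) did not pass. IRF8 (0.91, adjusted p = 0.628) and SPI1 (-0.11, 0.988) did not pass either. DNTT lost its call without any 1 of the CDP libraries (adjusted p = 0.0669 to 0.0930) and PAX5 without any 1 of the 6 libraries (0.0556 to 0.112). In all, 13 genes were higher and 2506 lower, of which 2017 were at 0 in all CDP libraries. Leaving out any 1 of the BNK libraries left 1 gene higher, and the covariate gave 188 higher and 295 lower. The covariate ended the calls of DNTT, IL7R, EBF1 and LTB (adjusted p = 0.193 to 1) and turned PAX5 (3.15, adjusted p = 1), while IRF8 passed with it (9.23, 0.00234). PAX5 was at 0 in all CDP libraries, so its turned sign comes from the covariate, which cannot be separated from CDP. The early lymphoid list had 5 of 23 genes lower (11 adjusted over the list alone, median -1.98, camera adjusted p = 5.73e-04) and the B cell list 4 of 23 (6 adjusted over the list alone, median -6.64, or -2.36 at the bound, 0.00115). The loss was not limited to lymphoid lists. The stem cell list had 12 of 28 genes lower (19 adjusted over the list alone, median -7.09, or -2.87 at the bound, camera adjusted p = 4.1e-05). The red cell and platelet list was lower in 12 of 12 genes (median -7.98, or -2.76 at the bound, adjusted p = 0.0423). None of these lists passed with an estimated correlation. The MHC class II list had a median of -0.05 while camera ranked it higher (adjusted p = 0.0227; 0.638 with an estimated correlation), because the median over all genes was -5.01, or -4.80 with RLE factors.

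MLP against LMPP addressed lymphoid commitment. In the 16 libraries (2 MLP, 2 LMPP), IL7R rose from 2.69 ± 0.177 to 15.9 ± 11.6 CPM and MME, the CD10 antigen of lymphoid progenitors, from 40.4 ± 38.3 to 221 ± 38.9. CSF3R fell from 224 ± 67.8 to 59.3 ± 26.6 CPM, and the stem cell genes MECOM and MLLT3 from 16.2 ± 3.32 to 2.58 ± 1.96 and from 166 ± 47.3 to 54.5 ± 3.09. The replication licensing genes MCM3 and CDC6 fell from 72.7 ± 20.6 to 13.9 ± 4.66 and from 10.8 ± 4.89 to 0, at least 38.6-fold for CDC6. IRF8 (264.8 ± 69.7 and 153 ± 17.3, adjusted p = 0.869) and SPI1 (33.5 ± 1.09 and 75.2 ± 39.96, adjusted p = 0.329) did not pass. That fit gave 17 genes higher and 98 lower. On all libraries edgeR called 0, with 941 at an unadjusted p under 0.05, DESeq2 29 higher and 131 lower, and limma-voom 3 and 9. The cell cycle list was lower by camera (median -2.29, or -1.64 at the bound, adjusted p = 4.1e-05), with adjusted p = 0.369 with an estimated correlation, and so was the red cell and platelet list (9 of 12 genes, -0.76, 0.00639; 0.488).

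BNK against MLP addressed the B cell and natural killer branch. In the 16 libraries (3 BNK, 2 MLP), DNTT rose from 3.16 ± 4.47 to 261 ± 203 CPM, IL7R from 15.9 ± 11.6 to 241 ± 150.2, EBF1 from 27.6 ± 3.52 to 176 ± 106, AKAP12, a scaffold protein of early B cells, from 0.965 ± 1.37 to 93.2 ± 27.5 and PAX5 from 1.31 ± 1.41 to 39.5 ± 25.6. BLNK, a B cell adaptor, RAG2, of the recombinase, and CD9, a tetraspanin, were at 0 in both MLP libraries and at least 181-fold, 61.3-fold and 45.7-fold higher in BNK. MKI67 rose from 19.9 ± 15.9 to 135 ± 67.6 CPM and MPO from 3.51 ± 2.52 to 133 ± 50.6, while HLF fell from 86.5 ± 0.593 to 25.1 ± 13.2. IRF8 (adjusted p = 1) and SPI1 (0.268) did not pass. That fit gave 270 genes higher and 21 lower. On all libraries edgeR called 0, with 926 at an unadjusted p under 0.05, DESeq2 137 higher and 5 lower, and limma-voom 628 and 43. In the 16 libraries camera called the B cell list higher at the preset correlation but not with an estimated one (adjusted p = 0.0781). On all libraries the B cell list was higher by camera (median 3.13, or 2.56 at the bound, adjusted p = 3.05e-14), also with an estimated correlation (adjusted p = 0.0380). There 0 of its 23 genes were called, and 1 adjusted over the list alone. Lists of other cells were higher with it: red cell and platelet in 12 of 12 genes (median 2.35, or 2.28 at the bound, adjusted p = 1.04e-04), mature B and plasma cell in 8 of 8 (6.33, or 3.06 at the bound, 4.05e-05), NK, T and innate lymphoid (2.07, or 1.72 at the bound, 7.24e-05), monocyte (1.601, or 1.02 at the bound, 5.68e-04), granulocyte (4.68, or 1.46 at the bound, 9.26e-04), erythroid and megakaryocytic (1.74, or 1.35 at the bound, 0.00208), endothelial and stromal (2.14, or 1.48 at the bound, 0.0119) and conventional dendritic cell (1.91, or 0.77 at the bound, 0.0414). None of these 8 passed with an estimated correlation (adjusted p = 0.0952 to 0.609). The BNK libraries detected 20016 genes on average and the MLP libraries 13602, and the list tests do not separate this gap from expression. With the number of genes detected as a covariate on all libraries, DNTT, IRF8 and SPI1 turned (-1.97, -2.34 and -0.40), none past the threshold. The other genes named here kept their direction. The cell cycle list was also higher by camera, in 24 of 30 genes (median 1.96, adjusted p = 8.87e-06; 0.369 with an estimated correlation). The median over all genes was 0.25, and 0.12 with RLE factors.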

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

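The fits without libraries under 6000 or 12000 genes, the covariate and the library sizes without MIR4485 were chosen after seeing the data. Of 132 values of named genes, 42 were past the threshold, and of these RLE kept 41, no filter 30, DESeq2 42, limma-voom 41, the fit of only the 2 populations 30 of 41, MIR4485 out of library sizes 42 and the covariate 18. With 1 library left out, 192 of 239 values kept their call. Settings did not give 103 values, which are those of CDP in the 2 fits without few-gene libraries, where CDP has no library, and 3 genes absent from the fit of only the 2 populations, and DESeq2 gave no adjusted p for 1. The ratio of SPI1 to IRF8 stayed past the threshold in every setting tried (F of 6.47 and 7.63 with pseudocounts of 0.5 and 5, and from 5.89 to 9.77 with 1 library left out). It was not tested with all few-gene libraries left out or with the covariate. Depth limits the low genes: by counting error alone, a gene at 0 in 3 libraries is known only to lie under the floor. Loss of transcripts before counting is not covered, so a gene at 0 in CDP can be expressed above the floor. Where no cause is named below, the cause was not tested. No paired analysis was possible because the replicate numbers are the order of the accessions and the labels give no shared origin.

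With DESeq2 the numbers of genes called were 291 (MPP against HSC), 363 (LMPP against MPP), 383 (CMP against MPP), 123 (GMDP against CMP), 128 (GMDP against LMPP), 417 (MDP against GMDP), 3774 (CDP against MDP), 4912 (CDP against GMDP), 160 (MLP against LMPP), 142 (BNK against MLP) and 4443 (CDP against BNK), with 1572 varying over the 9 populations; IRF8 in BNK against MLP was at -0.055 and SPI1 in CDP against BNK at 0.42, as with RLE (-0.055 and 0.42). With limma-voom the numbers were 71 (MPP against HSC), 74 (CMP against MPP), 271 (GMDP against CMP), 34 (GMDP against LMPP), 154 (MDP against GMDP), 5197 (CDP against GMDP), 12 (MLP against LMPP), 671 (BNK against MLP) and 6575 (CDP against BNK). It turned the log2 fold changes of SPI1 against HSC in CDP (-2.72) and MLP (-0.20), of IRF8 in CMP against MPP (1.81) and BNK against MLP (-0.15), and of LYZ in MDP against GMDP (-0.71). No filter gave 1389 varying genes, and an estimated correlation left 3 list tests of 67. With only the 2 populations compared, 2 genes were called in MPP against HSC, 1 in GMDP against CMP and 5184 in CDP against BNK, and IRF8 against HSC lost its call in LMPP (3.59, adjusted p = 0.154), MDP (4.06, 0.0581), CDP (5.49, 0.0581), MLP (4.67, 0.0983) and BNK (4.80, 0.0983), with fewer samples in the fit.

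Without the libraries under 12000 genes, the numbers were 182 (MPP against HSC), 244 (LMPP against MPP), 698 (CMP against MPP), 174 (GMDP against CMP), 585 (GMDP against LMPP), 777 (MDP against GMDP), 115 (MLP against LMPP) and 291 (BNK against MLP), with 2955 varying genes. Against HSC, with adjustment over the IRF8 and SPI1 tests, IRF8 in CMP (-2.03) and GMDP (1.75) and SPI1 in GMDP (1.06) passed. SPI1 in GMDP did not pass over all genes tested. SPI1 in MDP was at 1.77, given as a fold only because MDP had 1 library there. SPI1 in MLP (-0.37), NRIP1 in MPP against HSC (-0.33) and IRF8 in BNK against MLP (-0.14) turned. Without those under 6000 genes, 4 genes were called in LMPP against MPP and 14 in MDP against GMDP, with 159 varying, and IRF8 against HSC lost its call in LMPP (3.02, adjusted p = 0.190), MDP (3.47, 0.183), MLP (4.12, 0.148) and BNK (4.21, 0.148), while SPI1 in MLP turned (-0.12). With the covariate, 549 genes were called in CDP against MDP (163 higher, 386 lower), 624 against GMDP (241 and 383) and 483 against BNK (188 and 295), IRF8 passed in GMDP against HSC (3.65), and these turned: IRF8 and MEIS1 in MPP against HSC (0.67 and 0.83), SPI1 in LMPP and CMP against MPP (-0.42 and -0.32), GMDP against CMP (-0.066), BNK against MLP (-0.40) and CDP against MDP, GMDP and BNK (1.27, 2.21 and 3.39), IRF8 and DNTT in BNK against MLP (-2.34 and -1.97) and PAX5 in CDP against BNK (3.15).

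With 1 library left out, the number of genes called ranged from 0 to 1 in LMPP against MPP, 0 to 23 in MDP against GMDP and 1794 to 2151 in CDP against GMDP, and the number varying from 292 to 1552. IRF8 against HSC ranged from 2.99 to 4.12 in LMPP, 3.44 to 4.47 in MDP, 5.02 to 6.14 in CDP, 4.08 to 5.12 in MLP, 4.204 to 5.23 in BNK and -6.16 to -0.63 in MPP, where it passed without MPP replicate 1. SPI1 against HSC ranged from -0.18 to 1.17 in MLP and -1.32 to 1.89 in CDP, MEIS1 in MPP against HSC from -0.77 to 0.18, IRF8 in CMP against MPP from -1.41 to 4.15, SPI1 in GMDP against CMP from -0.016 to 0.51 and against LMPP from -0.10 to 0.39, LYZ in MDP against GMDP from -2.81 to 2.41, PACSIN1 in CDP against MDP from 0 to 12.78, SPI1 in CDP against GMDP from -2.98 to 0.031 and against BNK from -2.57 to 0.45, IRF8 in BNK against MLP from -0.13 to 0.45 and CD74 in CDP against BNK from -0.23 to 0.51.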

Other observations

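The tests of list genes under shuffled labels, of the covariate in CDP, of CD34, of IRF8, of the common dispersion and of MIR4485 were chosen only after the result was seen. Plasmacytoid dendritic cell genes differed between the CDP libraries: in CDP replicate 1 the surface lectin CLEC4C stood at 137 CPM, the receptor LILRA4 at 106, the transcription factor SPIB at 126 and PACSIN1 at 170.2, and all 4 were at 0 in CDP replicates 2 and 3. TCF4 was read in all 3, at 1410.0, 777 and 333 CPM.

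Monocyte and red cell genes differed between the MPP libraries. LYZ was at 18.2, 139 and 435 CPM in MPP replicates 1, 2 and 3, FCN1, a monocyte lectin, at 1.65, 53.7 and 169, VCAN, a proteoglycan of monocytes, at 9.24, 53.5 and 217, and HBB, the adult beta globin, at 17.6, 102 and 244. The cause was not tested.

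More genes were lower than higher in CDP, and 2 technical explanations were weighed. With the number of genes detected as a covariate, 61.4% of the genes called in CDP against GMDP were lower instead of 96.8%. Outside CDP only HSC replicate 1 had under 6000 genes, so that fit cannot separate the number of genes from CDP. Of 7022 genes with a mean of at least 10 CPM in GMDP and in HSC replicates 2 and 3, 1370 were at 0 in all 3 CDP libraries and 1272 in CDP replicates 1 and 2 and HSC replicate 1, a ratio of 1.08 (1658 and 1617 with HSC replicate 1 in place of CDP replicate 2 or 1), so few detected genes fit as an explanation of most of the lower genes. CD34 kept its call with the covariate (adjusted p = 3.05e-08), which counts against a trend with the number of genes as its whole cause, but so did RPS13 and COX6C, housekeeping genes also at 0 in all CDP libraries, so the test does not set CD34 apart from lost transcripts. HSC replicate 1, with 3981 genes, held 1317 reads of CD34, but a single library excludes nothing, and loss of transcripts, CD34 RNA absent from the cells sorted as CDP, and another population sorted in its place all stay open.

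Few genes passed between the 8 other populations. Leaving out the 10 libraries under 12000 genes gave 3066 genes over the 8 comparisons, but 10 of 40 choices of as many libraries from each population, this one included, gave as many, up to 16309, so the count does not single out these libraries. The common dispersion of 0.887 was the lowest of the 40 choices, and only 1 of the 40, this choice itself, reached it. The next, 0.893, came from a choice that kept 1 of the 10 libraries in. With so small a difference, the dispersion does not single out exactly these 10 libraries either. The choices that kept 2 of them in gave 1.06 and 1.08. No biological explanation was tested.

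IRF8 was higher than in HSC in several populations, and few detected genes in some libraries were weighed as the cause. Without the 10 libraries under 12000 genes, 5 of 5 contrasts (LMPP, GMDP, MDP, MLP and BNK) were higher and past the threshold, with log2 fold changes of 3.54, 1.75, 3.42, 4.34 and 4.202. With all libraries they were 3.58, 2.34, 4.03, 4.68 and 4.79. Without the 4 libraries under 6000 genes the calls in LMPP, MDP, MLP and BNK were lost, so the calls depend on which libraries are fitted while the direction did not change. The folds that remained without the 10 libraries argue against few detected genes as the cause in GMDP, MLP and BNK. For LMPP they cannot decide, because the cut removed LMPP replicate 2. That library had 11086 genes and IRF8 at 7.81 CPM, under HSC replicates 2 and 3 at 12.03 and 11.56. MDP had a lone library without the 10 libraries.

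The share of counts in the MIR4485 row fell as the number of genes detected rose (Pearson -0.729, permutation p = 6e-05), also within populations (-0.760, permutation p = 0.00887; 5 correlations were computed, and adjusted over them this is 0.00887). The libraries of 2 populations have only 10 splits, the real one included, too few for a share under 0.05. The real split called 2704 genes in CDP against GMDP and 2519 in CDP against BNK, reached by 1 of 10 splits each, with 0 in every other split. In MPP against HSC, LMPP against MPP, CMP against MPP, GMDP against CMP, GMDP against LMPP, MLP against LMPP and BNK against MLP the real split called 0, which all 10 of 10 splits reach, and the highest other splits gave 919, 0, 3, 0, 0, 0 and 0. The 919 came from the split that put HSC replicate 1 and MPP replicates 2 and 3 together. Over the 9 populations, 485 genes varied, and 2 of 60 label sets, the real one included, called as many, the highest other giving 512. Every shuffled label set also called genes, at least 90. The adjusted p of this F test thus does not hold the share of false calls at 0.05, and part of the 485 can be false. The real labels called 50 list genes, reached by 1 of 60, the highest other giving 23.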
